A study of Homo sapiens with 3 samples.

How the data were processed

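SOX4, a high-mobility-group transcription factor, was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in BT549, an established human triple-negative breast cancer cell line. The 3 libraries form 1 group and are named replicates 1, 2 and 3 after their titles. Per the labels and the series design, chromatin was fixed with DSG and then formaldehyde, sonicated, and immunoprecipitated with an Abcam SOX4 antibody, and paired-end reads were sequenced on an Illumina NextSeq. The labels do not say whether the libraries came from separate cultures, so any spread between them may be technical. No second condition and no input or IgG library was analysed here, so every comparison is between libraries, between positions in the genome, or between groups of genes.

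Each library came with 1 list of summits of 1 bp, made per library by the authors rather than on pooled reads. Per the submitters' processing notes, BWA, SAMtools and MACS2 were used, with no versions given. The deposited value per summit is a −log10 of a p or q value, as MACS2 writes it; which of the 2 it is was not given in the sources used here. This score is the authors' own and was used only to describe, rank and filter summits within a list. Read numbers, peak widths and enrichment over a control were not used here, so the sequencing depth is unknown and intervals cover counting error only. The peak numbers in each list run from 1 to its number of summits, with none missing, so no filter after peak calling was seen.

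The submitters' notes name hg19, but the positions are those of GRCh38. The lists use 54 contig names, 41 of them with KI270 identifiers that belong to GRCh38, and their highest positions on chromosomes 17, 20 and X (83247361, 64088674 and 156030493) lie past the chromosome ends of hg19 and near the last genes of the GRCh38 table. Positions are given 1-based on GRCh38. Genes came from a RefSeq table of GRCh38.p14 with 20037 protein-coding symbols on the assembled chromosomes. That table gives the start and end of each gene and no strand, so the planned distance to a transcription start site was replaced by the distance to either gene end. Exons, introns and untranslated regions were not told apart. All members of the 16 gene lists fixed before the data were examined were found in the table.

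A summit counted as shared when another library had a summit within 200 bp, because summits have no width to overlap. Summits of all libraries linked by gaps of at most 200 bp were joined into regions, and a region was reproducible when at least 2 libraries contributed. Distances of regions are from their midpoints. Overlaps and distances were compared with 1000 seeded random placements that kept each summit's chromosome, with one-sided p-values whose smallest possible value is 0.001. Scores of shared and unshared summits were compared by the difference in medians with a two-sided permutation test of 100000 resamples in each list, with Benjamini-Hochberg adjustment over the 3 lists. Each of 15 gene lists was tested by a two-sided Fisher's exact test for genes with a reproducible region within 5 kb of either end, against all 20037 coding genes, with Benjamini-Hochberg adjustment over the lists. The 8 genes named in the series design received distances and counts only, since the study chose them on these libraries. Intervals of shares are exact 95% binomial intervals.

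The text names the 8 genes of the series design, at most 6 members of each list with a reproducible region within 5 kb (regions of 3 libraries first, then by distance), and the 20 regions of all 3 libraries with the best worst rank by score. Genes named outside that rule are marked as chosen after their values were seen. Alternatives fixed before the data were examined changed the score threshold, the list length, the number of libraries required, the distance, the gene set and the random lists, and left out each library in turn. Other windows, placement at gene ends, gene spans, chromosome-matched lists, summits of 2 libraries at any distance from each other and subsets of chromosomes were added after the data were seen, as was leaving out libraries for the families and for the lists with any library. The planned test of 13 sequence motifs, the matching on promoter CpG content, the overlap by peak length and the comparison within classes of peak width were not run, because no genome sequence or peak width was used here.

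The steps were tested on simulated data. Of 300 shared summits planted in lists with the sizes of replicates 1 and 2, the step counted 310 as shared, and 12 when none were planted. With 50% of reproducible regions planted at gene ends, 50.8% were found within 1 kb. For lists of 50 genes among 20037, the Fisher test passed an unadjusted 0.05 in 2.5% of simulations at a true fold of 1, in 73.5% at a fold of 4 and in 99.5% at a fold of 8. Smaller lists, adjusted p-values and neighbours that share a region were not simulated. These rates therefore do not carry over to the immune lists tested here. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.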

Results

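SOX4 ChIP-seq in BT549 cells gave 1368 summits in replicate 1, 1713 in replicate 2 and 4430 in replicate 3, a mean of 2504 ± 1677 (SD, n = 3). The authors' score, a −log10 of a p or q value, had a median of 6.12, 5.57 and 5.58 in the 3 lists and a maximum of 160, 179 and 111. Scores above 20 were held by 7.68% of the summits of replicate 1, 6.13% of replicate 2 and 1.78% of replicate 3. The longer list of replicate 3 held fewer strong summits, 79 against 105 in each of the other libraries. The summits on assembled chromosomes numbered 1264, 1588 and 4304, and the rest lay on contigs outside them or on the mitochondrial genome.

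The first comparison asked how far the libraries placed SOX4 at the same sites. Replicates 1 and 2 shared 485 summits of replicate 1 (35.5%) within 200 bp. Replicate 3 held 545 summits of replicate 1 (39.8%) and 559 of replicate 2 (32.6%). Seen from its own longer list, replicate 3 shared 12.3% of its summits with replicate 1 and 12.6% with replicate 2. Random placement on the same chromosomes gave means of 14.1, 11.1 and 12.3 shared summits for the 3 pairs and never more than 26. Placing the summits near gene ends at other gene ends of the same chromosome raised these means to 18.7, 28.4 and 28.6. Each pair exceeded every one of the 1000 placements of both kinds (one-sided permutation p = 0.001, the smallest they can give).

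**Figure D1:**
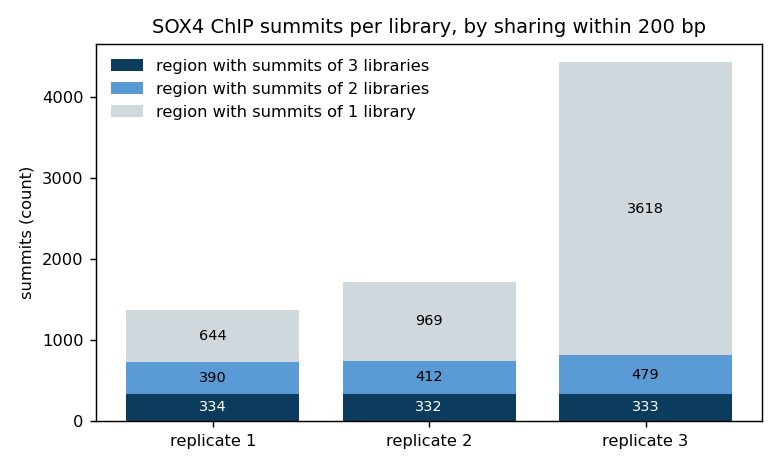
Number of SOX4 summits (y axis) in each library (x axis), with colours for summits in regions of 1, 2 or 3 libraries joined within 200 bp. Replicate 3 has 3618 summits seen in no other library, against 644 in replicate 1 and 969 in replicate 2.

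Joined over the libraries, the summits formed 6199 regions, of which 5229 came from 1 library, 639 from 2 and 331 from all 3. The 970 regions of at least 2 libraries, called reproducible here, made up 15.6% of all regions, against a mean of 28.01 and a maximum of 43 under random placement. Of them, 868 lay on assembled chromosomes, 92 on contigs and 10 on the mitochondrial genome. Leaving out 1 library lowered the count, to 559 regions without replicate 1, 544 without replicate 2 and 480 without replicate 3. Within each list, shared summits scored higher than unshared ones. The medians were 7.48 against 5.39 in replicate 1, 7.02 against 5.21 in replicate 2, and 7.23 against 5.33 in replicate 3 (two-sided permutation tests, adjusted p = 1e-05 in each list, the smallest they can give). Scores above 20 were held by 14.2%, 14.0% and 9.11% of the shared summits and by 0.311%, 0.103% and 0.138% of the others.

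The strongest sites common to all 3 libraries lay over 1 kb from the ends of protein-coding genes. Of the 20 regions ranked highest in every list, 14 were on assembled chromosomes, 3 on contigs and 3 on the mitochondrial genome. None of the 14 lay within 1 kb of a coding gene end, and 8 were over 50 kb from one. The highest was at chromosome 3, 93470597 to 93470602, with scores of 128, 146 and 110 in replicates 1 to 3, 402 kb from PROS1. The region at chromosome 16, 46390475 to 46390513, scored 160, 179 and 50.98 and lay 188 kb from SHCBP1. The region at chromosome 4, 190179539 to 190179694, fell inside DUX4, a repeat-encoded homeobox gene, with scores of 84.3, 112 and 111. At chromosome 1, 631106 to 631130, the region overlapped MTCO1P12, a nuclear pseudogene of a mitochondrial gene, and the protein-coding gene LOC102724250. Regions nearer to coding genes were those at chromosome 18, 108254 to 108258, inside a long non-coding RNA gene, and at chromosome 11, 10509478 to 10509511, 1.92 kb from an end of AMPD3. The region at chromosome 8, 144125868 to 144125876, lay 7.54 kb from WDR97. The remaining assembled regions included those near NID1 at 32.1 kb, FRG2B at 62.8 kb, ZNF33B at 714 kb and EMB at 730 kb, and a pair at chromosome 1 around 143214594 and 143263538. Regions on contigs or the mitochondrial genome made up 19.0% of the regions of 3 libraries, 6.10% of those of 2 and 1.64% of those of 1.

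The next question was whether the summits lie at the ends of genes, where promoters are found. They did so far above chance in all 3 libraries. Within 1 kb of a coding gene end lay 40.7% of the summits of replicate 1, 29.2% of replicate 2 and 54.9% of replicate 3 (mean 41.6% ± 12.9, SD, n = 3), against 2.40%, 2.22% and 2.37% under random placement. Of the 868 reproducible regions on assembled chromosomes, 420 lay within 1 kb (48.4%, 95% interval 45.0 to 51.8%), against 2.42% at random. Within 5 kb the share was 54.3%. Every one of these shares exceeded all 1000 placements (one-sided permutation p = 0.001, the smallest they can give). Regions of all 3 libraries had a lower share within 1 kb, 35.8% (30.1 to 41.9%), than regions of 2 libraries at 54.0% (49.9 to 58.0%) or of 1 library at 46.8% (45.4 to 48.1%). The share of summits over 50 kb from a coding gene end was 33.6% in replicate 1, 42.0% in replicate 2 and 21.6% in replicate 3. Which end of a gene is its start was not known here, so the shares count both.

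**Figure D2:**
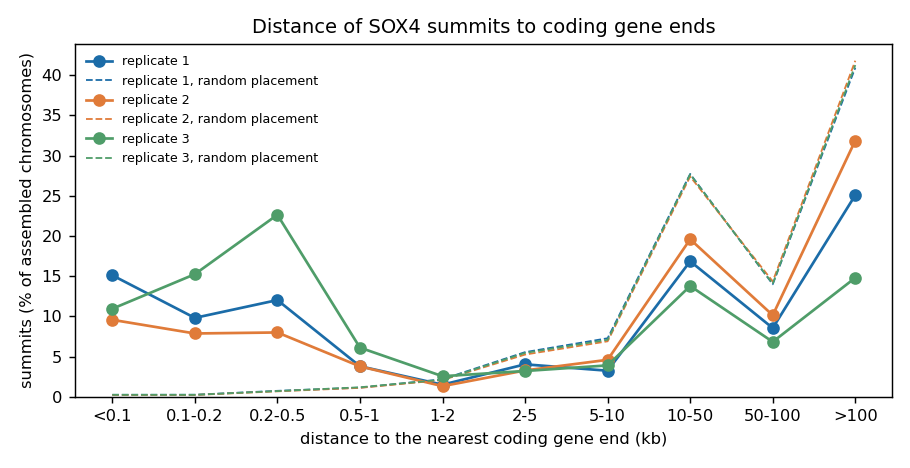
Percent of the summits of each library on assembled chromosomes (y axis) by distance to the nearest coding gene end in kb (x axis, classes of unequal width), as points and solid lines, with the mean of random placements as dashed lines. Summits exceed the placements in each class up to 1 kb, where they hold 40.7%, 29.2% and 54.9% of the lists.

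Chromosome 8 carried far more summits than its size. It held 23.02% of the assembled summits of replicate 1, 36.4% of replicate 2 and 16.8% of replicate 3, with 4.70% of the length and 3.57% of the coding genes. Summits over 1 kb from coding gene ends had a density of 1.44, 3.34 and 3.36 per Mb there in replicates 1 to 3. The median of the other autosomes was 0.155, 0.182 and 0.478 per Mb, and the highest of them was chromosome 9 with 0.448, 0.658 and 1.53. Of the coding genes on chromosome 8, 36.8% had a summit within 1 kb in any library, against 15.1% of all coding genes.

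**Figure D3:**
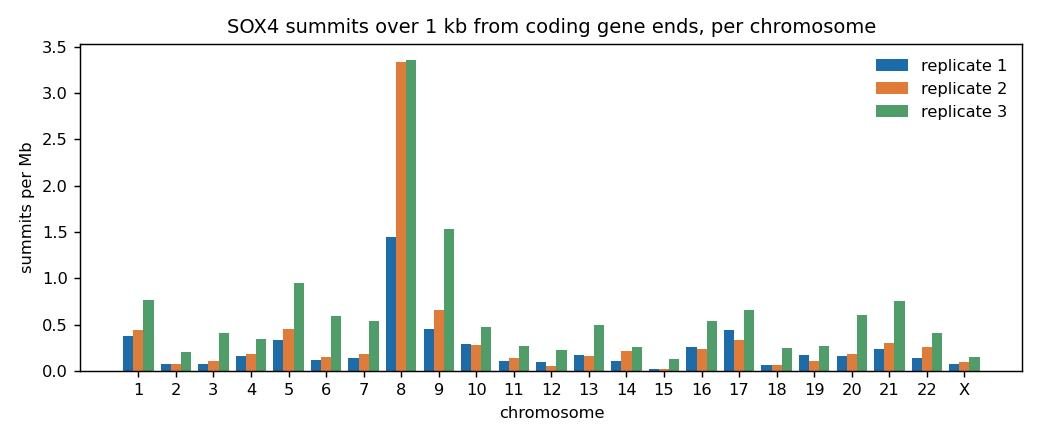
Summits over 1 kb from coding gene ends per Mb (y axis) on chromosomes 1 to 22 and X (x axis), with 1 bar per library. Chromosome 8 stands at 1.44, 3.34 and 3.36 per Mb in replicates 1, 2 and 3, above every other chromosome of the same library.

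The series design names 8 genes as carrying SOX4 sites in their regulatory regions: the RNA sensor gene IFIH1, the interferon-pathway genes IRF7 and ISG15, and the MHC class I pathway genes HLA-B, HLA-C, PSMB9, TAP1 and TAP2. With summits taken within 5 kb of either gene end, 1 of the 8 genes had a summit in any library and 0 of 8 in at least 2 libraries. It is not clear which distance, gene table or build the authors used, so this count is no like-for-like check of their statement. TAP2, a subunit of the peptide transporter of antigen processing, had a summit of replicate 3 at chromosome 6, 32838654, inside the gene and 85 bp from its end. Its score of 3.55 stood above 5.64% of the summits of that list, and the nearest summits of replicates 1 and 2 were 3189 kb and 1455 kb away. The same summit was the nearest of replicate 3 to TAP1, at 6.56 kb, and to PSMB9, at 15.5 kb. HLA-B had a replicate 2 summit at 10.1 kb (chromosome 6, 31367264, score 3.09), which was also the nearest of that list to HLA-C, at 95.2 kb. IRF7 was the 1 gene with a summit within 50 kb in all 3 libraries, at 27.1 kb in each of them. Those summits lay at chromosome 11, 585415, 585469 and 585438, inside PHRF1, with scores of 6.32, 10.4 and 7.44. ISG15 had a replicate 2 summit at 46.7 kb, inside PLEKHN1 and 347 bp from an end of that gene. The nearest summit to IFIH1 was 986 kb away, in replicate 3, and the nearest to the SOX4 gene itself was 480 kb away, also in replicate 3.

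Widening the distance to 10 kb gave 2 of the 8 genes with a summit in any library and 50 kb gave 6. In at least 2 libraries the counts were 0 and 1. Among all coding genes, 17.8% had a summit of any library within 5 kb, 20.2% within 10 kb and 34.4% within 50 kb. The study chose the 8 genes on these libraries, so their count is not independent evidence, and no test was made of them.

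**Figure D4:**
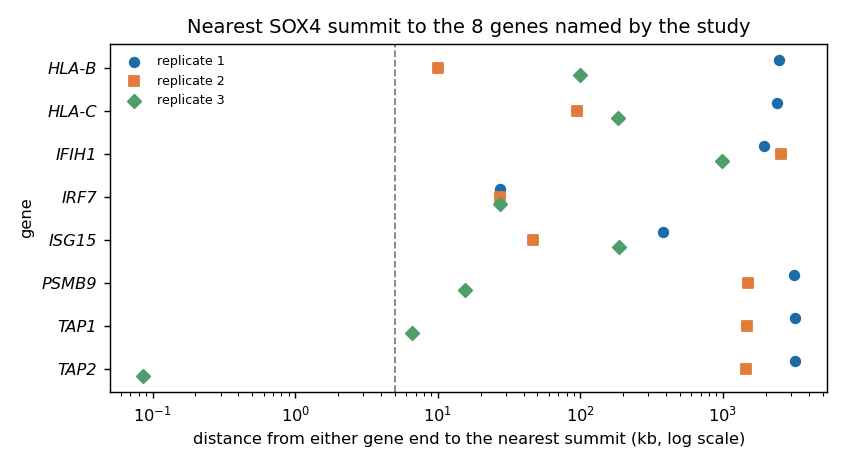
Distance in kb (x axis, log scale) from either end of each of the 8 genes named by the study (y axis) to the nearest summit, with 1 marker per library and a dashed line at 5 kb. TAP2 in replicate 3 is the 1 point left of the line, and the 3 markers of IRF7 coincide at 27.1 kb.

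The same question was then put to whole groups of genes fixed before the data were examined. Among reproducible regions, the immune groups were not above the 2.97% of all coding genes (596 of 20037) within 5 kb. MHC class I antigen processing had 0 of 22 genes (exact upper limit 15.4%), MHC class II 0 of 15 (21.8%), and cytosolic and endosomal nucleic acid sensing 0 of 27 (12.8%). Interferon signalling had 1 of 54 (1.85%, 95% interval 0.0469 to 9.89%), the type I interferon receptor gene IFNAR1. Its region at chromosome 21, 33324500 to 33324523, scored 3.601 in replicate 1 and 4.87 in replicate 3. Each of these 4 lists had an adjusted p of 1 by Fisher's exact test. With under 2 genes expected in each, a lower share than that of all genes was not detectable.

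Replication-dependent histone genes, which package newly made DNA, stood out. They had 22 of 69 genes near a reproducible region (31.9%, 95% interval 21.2 to 44.2%), 10.7 times the share of all coding genes (two-sided Fisher's exact test, adjusted p = 4.2e-16). The 22 genes shared 15 distinct regions, all in the clusters of chromosomes 1 and 6. Fisher's exact test counts these neighbours as separate genes, so its p-value may be too small. Without replicate 3 the histone list had 5 of 69 genes (ratio 6.82, exact adjusted p = 0.0126), without replicate 1 it had 11 and without replicate 2 it had 16. H4C14 had summits of replicates 1, 2 and 3 at 91, 115 and 34 bp from its ends, with scores of 12.1, 4.605 and 7.19. H4C12 had them at 10, 114 and 156 bp, with scores of 5.34, 5.29 and 19.95. The next in order of the distance of the region midpoint were H4C2, H4C8, H4C11 and H2AC15, each with 2 libraries and a midpoint at most 168 bp from a gene end. Olfactory receptor genes, fixed as a list of genes not used in breast cells, had 1 of 390 (0.256%, 0.0862 times the share of all genes, exact adjusted p = 0.00156), OR2T1, whose region was in all 3 libraries with scores of 14.9, 12.4 and 12.8. Where all 3 libraries were required, neither list passed, with 0 of 15 lists at an adjusted and 0 at an unadjusted p under 0.05 by Fisher's exact test. The ratios were then 3.92 for the histone genes and 0.347 for the olfactory receptors. The olfactory receptor list also lost its call without replicate 2 (ratio 0.149, exact adjusted p = 0.0827), without replicate 3 (0.241, p = 0.679) and with only the summits at or above the median score (0.201, p = 0.485). It had 1 of 390 genes in each of these settings, against 6.72, 4.15 and 4.96 expected, and 11.6 expected with all libraries and summits.

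Genes of epithelial and mesenchymal state had 4 of 30 members near a reproducible region (13.3%, 95% interval 3.76 to 30.7%, 4.48 times the share of all genes), which missed the threshold after adjustment (exact p = 0.0115, adjusted p = 0.0575). They were CTNNB1, which encodes beta-catenin, EZH2, a histone methyltransferase gene, VIM, which encodes the mesenchymal filament vimentin, and GRHL2, an epithelial transcription factor gene. The midpoint of the CTNNB1 region lay 15 bp from the lower coordinate of the gene, with scores of 6.76 in replicate 1 and 4.92 in replicate 3. The Wnt list had 3 of 33 (9.09%, exact adjusted p = 0.277): DKK1, a secreted Wnt inhibitor gene, in all 3 libraries with scores of 2.99, 5.85 and 6.40, the receptor gene FZD6 and the kinase gene GSK3B. Genes of AP-1, TEAD and YAP had 2 of 25 (8.0%, exact adjusted p = 0.424), CCN1 and YAP1. The TGF-beta list had 1 of 30, SKIL (exact adjusted p = 1), and the luminal breast list 1 of 16, MUC1 (adjusted p = 0.821). Cytosolic ribosomal proteins had 5 of 86 (5.81%, exact adjusted p = 0.340): RPS20, RPS19, RPS6, RPS15A and RPL41. The SOX family had 0 of 20, cell cycle genes 0 of 35 and blood lineage genes 0 of 26, each with an exact adjusted p of 1.

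Counting a summit of any 1 library changed the picture for MHC class I genes. Then 10 of 22 lay within 5 kb (45.5%, 95% interval 24.4 to 67.8%), against 17.8% of all coding genes (ratio 2.55, two-sided Fisher's exact test, adjusted p = 0.00948). Replicate 3 gave 9 of the 10: B2M, the light chain gene of MHC class I, HLA-E, PDIA3, PSMB8, PSME1, PSME2, TAP2, TAPBP and ERAP1. Replicate 1 gave CALR, and replicate 2 gave ERAP1, 216 bp from its end. These genes were named after their values were seen. PSMB8 and TAP2 shared 1 replicate 3 summit, at 2063 and 85 bp, and PSME1 and PSME2 shared another, at 2254 and 2149 bp. Fisher's exact test counts such neighbours as separate genes, so its p-value may be too small. Without replicate 3, 2 of the 22 remained near a summit of any library (9.09%, against 5.75% of all coding genes, ratio 1.58, exact adjusted p = 0.727). Against random lists matched on gene density the permutation p was 0.0112 after adjustment, and against lists matched on chromosome, added after the data were seen, 0.0595. MHC class II genes had 0 of 15, innate sensing 5 of 27 (exact adjusted p = 0.810) and interferon signalling 6 of 54 (adjusted p = 0.386). Ribosomal proteins also passed, with 35 of 86 (40.7%, exact adjusted p = 2.9e-06), as did histones with 57 of 69 (82.6%, adjusted p = 1.8e-30). Olfactory receptors, with 2 of 390 (exact adjusted p = 1.7e-29), and blood lineage genes, with 0 of 26 (adjusted p = 0.0276), were below the share of all genes. The blood lineage list stayed at 0 of 26 and lost its call without replicate 3 (1.496 genes expected against 4.63, exact adjusted p = 0.727) and against lists matched on chromosome (3.81 expected, permutation p after adjustment 0.0595). Without replicate 3, ribosomal proteins had 12 of 86 genes (exact adjusted p = 0.0185) and histones 24 of 69 (3.9e-12).

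**Figure D5:**
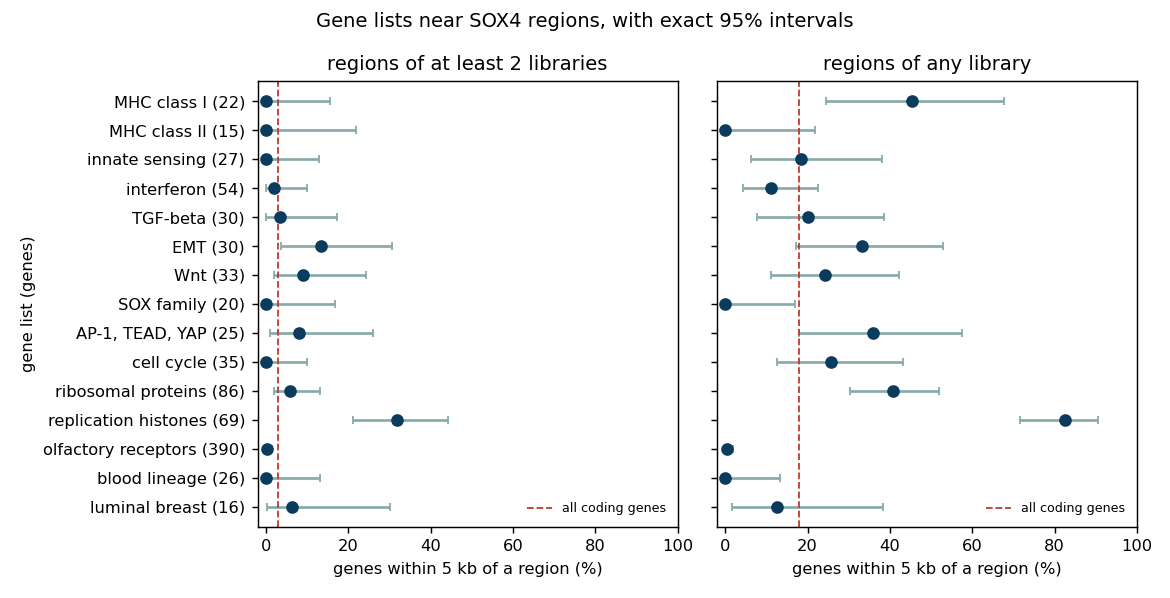
Percent of the genes of each list (y axis, number of genes in brackets) within 5 kb of a reproducible region (left) or of a region of any library (right), as points with exact 95% intervals, and the percent of all coding genes as a dashed line. MHC class I genes stand at 0% on the left and 45.5% on the right, and histone genes at 31.9% and 82.6%.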

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

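The test of contig shares was chosen after its result was seen; the test of neighbouring sites was not. Summits outside the assembled chromosomes are a signal that the comparisons with genes leave out. Contigs held 94 summits in replicate 1, 115 in replicate 2 and 115 in replicate 3, and the mitochondrial genome held 10, 10 and 11. No control library was analysed here to set a background for them, so no test against one was made.

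Of the 20 strongest regions of all 3 libraries, 6 lay on contigs or the mitochondrial genome and 8 over 50 kb from a coding gene end. A candidate explanation is reads from multicopy or unplaced sequence, which pile up on the copies that the assembly holds. The share of regions on contigs or the mitochondrial genome, 11.6 times higher among regions of 3 libraries than of 1, is part of the pattern and no independent test of it. Arrays of repeats may also give several sites close together. Of 96 regions of 3 libraries over 50 kb from a coding gene end, 59 had another region of 3 libraries within 100 kb, whatever its own distance from genes. Of 96 within 1 kb of a gene end, 4 did. That is 14.8 times as often (61.5% against 4.17%, Fisher's exact p = 9.8e-19). Neighbours come in pairs, so this p-value treats dependent regions as independent. No repeat annotation was used, so the count cannot tell repeats from other dense runs of summits, such as those of chromosome 8. No biological explanation was tested, and binding of SOX4 at these sites stays open without a control library. The genes named beside these regions, such as PROS1 at 402 kb and EMB at 730 kb, give their position only and were not tested as targets.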

How the results depend on the processing

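The windows of 100 and 500 bp, placement at gene ends, gene spans, chromosome-matched lists, summits in 2 libraries at any distance from each other, subsets of chromosomes, and leaving out libraries for families and for lists with any library were added after the data were seen. Of 356 alternative values, 292 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. All 15 values for shared summits, 6 for scores and 23 for gene ends did so. The share of reproducible regions within 1 kb was 35.4 to 48.0% with 1 library left out. Gene list enrichment gave 240 of the values, of which 200 kept their call. Lists such as MHC class II had 0 genes near, with 0.446 expected, and could not fall lower. The total is therefore weak evidence of stability. Reproducible regions numbered 331 in 3 of 3 libraries, 531 among summits at or above the median score and 480 to 559 with 1 library left out, since fewer summits or libraries enter. Of the 8 study genes, 1 had summits of 2 libraries at a distance of 50 kb, 1 with any 1 library, and 0 whichever library was left out. Lists past the threshold numbered 2, against 0 with 3 of 3 libraries, 1 with the median score, 5 with any 1 library and 1 to 2 with 1 library left out. Ratios of lists to all genes changed side of 1 as follows, and the cause was not tested. With any 1 library, MHC class I rose to 2.55, innate sensing to 1.04, cell cycle to 1.44, and luminal breast fell to 0.702. Interferon genes stood at 1.02 with the window of 500 bp and between 0 and 1.08 with 1 library left out. Innate sensing was at 1.02 with 500 bp, and MHC class I at 1.16 with summits in 2 libraries near the gene; with reproducible regions it stayed at 0 with each library left out. TGF-beta was at 0.981 at 10 kb, 0.917 with 500 bp and 0.960 with gene spans, and luminal breast at 0 at a distance of 1 kb. With 3 of 3 libraries, TGF-beta, EMT, AP-1, ribosomal and luminal lists were at 0, and with the median score TGF-beta, Wnt, AP-1 and luminal lists were at 0. With 1 library left out, TGF-beta ranged from 0 to 1.94, EMT from 0 to 5.81, AP-1 from 0 to 7.53 and luminal breast from 0 to 3.63. With any library, 21 of 25 values for the 5 lists past the threshold and 12 of 18 for the 6 families kept their call; for reproducible regions 0 of 3 did for the hnRNP and SR family and 2 of 6 for pooled families. Not run were the motif test, CpG matching, overlap by peak length and classes of width. Depth per library is unknown, so the lists cannot show whether replicate 3 was read more deeply.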

Other observations

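The tests on chromosome 8, on the length of the replicate 3 list and on housekeeping families without ZNF genes were chosen after their results were seen, the gene families after the summit lists had been examined, and leaving out libraries for them after their values were seen. Of 13 gene families, 1 lay near reproducible regions more often than other genes past the threshold. The hnRNP and SR splicing factors had 6 of 38 members within 5 kb (15.8%, 5.31 times the share of all coding genes, two-sided Fisher's exact test, adjusted p = 0.0108): SRSF10, HNRNPU, HNRNPA2B1, HNRNPK, HNRNPH3 and SRSF6. The call was lost without replicate 1 (3 of 38, exact adjusted p = 0.261), without replicate 2 (3 of 38, 0.274) and without replicate 3 (2 of 38, 0.801), at ratios of 4.59 to 5.17. With any 1 library they had 14 of 38 (36.8%, exact adjusted p = 0.0154), and 8 of 38 without replicate 3 (exact adjusted p = 0.0159). DEAD and DEAH box helicases had 1 of 54 near a reproducible region and RNA polymerase subunits 1 of 33, POLR3G. RNA polymerase subunits had 14 of 33 with any library (42.4%, exact adjusted p = 0.00369), and 4 of 33 without replicate 3 (exact adjusted p = 0.221), at ratios of 2.38 and 2.11. Translation initiation factors had 17 of 56 with any library (ratio 1.71, exact adjusted p = 0.0463), and 4 of 56 without replicate 3 (ratio 1.24, 0.770). Families were drawn by gene symbol, so this one includes EIF4EBP1, the gene of an eIF4E-binding protein. Keratins had 0 of 55, keratin-associated proteins 1 of 94 and defensins 2 of 45 with any library (exact adjusted p = 3.1e-04, 5.5e-06 and 0.0449). Without replicate 3 these were 0, 1 and 0 genes, at ratios of 0, 0.185 and 0, and the calls were lost (0.211, 0.193 and 0.221); defensins also lost theirs without replicate 1 (0.0558).

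Summits may favour the ends of genes active in most cells. For reproducible regions, 8 housekeeping families had 27 of 855 genes within 5 kb (3.16%) and 5 tissue-restricted families 2 of 269 (0.743%), a ratio of 4.25 (two-sided Fisher's exact test, p = 0.0270). The call was lost with each library left out: the ratio was 4.40 without replicate 1 (14 and 1 genes, exact p = 0.138), 2.99 without replicate 2 (19 and 2 genes, 0.193) and 2.52 without replicate 3 (8 and 1 genes, 0.695). Against all coding genes the 8 families were at a ratio of 1.06 (exact p = 0.757). Most of their genes are zinc finger genes named ZNF, with 7 of 509 (1.38%, ratio 0.462, exact adjusted p = 0.214), and the other 7 families had 20 of 346 (5.78%, ratio 1.94, exact p = 0.00562), or 6 of 346 without replicate 3 (ratio 1.63, 0.188). The ZNF genes were left out after their share was seen, and gene activity in these cells was not measured here, so the explanation stays open. Chromosome 8, with its excess of summits, was not left out of the family tests. Members near a reproducible region there include MRPS28 and NDUFB9, and their full number was not counted. How much of these ratios comes from that excess is therefore unknown.

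Of the regions of all 3 libraries on assembled chromosomes, 96 lay within 1 kb of a coding gene end. For the ranking, each gene was given only its nearest reproducible region, which left 94 of these regions at 113 genes. The strongest by worst rank after OR2T1 were at MTF2, with scores of 22.3, 20.9 and 11.7, at the shared end of MRPL57 and SKA3, with 31.2, 25.6 and 10.6, at MAK16 and at RICTOR, a subunit gene of the mTORC2 kinase. RBM39, which encodes a splicing factor, had scores of 80.2, 40.4 and 8.97. All were picked after their values were seen. Those up to RICTOR follow the rank, while RBM39 stands below PCMTD1, FNTA and ZNG1C, which are not described.

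Among summits over 1 kb from coding gene ends, 6 of replicate 1, 4 of replicate 2 and 25 of replicate 3 lay within 1 kb of a transfer RNA gene, against means of 0.184, 0.207 and 0.487 under random placement. The ratios were 32.6, 19.3 and 51.3 in replicates 1 to 3 (one-sided permutation p = 0.001, the smallest the 1000 placements can give, in each library). Small nuclear RNA genes had 14, 12 and 27 such summits, against means of 0.08, 0.109 and 0.171. Small nucleolar RNA genes were at ratios of 8.06, 6.23 and 6.72 and microRNA genes at 9.23, 4.63 and 8.13. Some excess was thus seen beyond transfer RNA genes, though at lower ratios in these last classes. The difference between classes was not tested. Many of these genes have near-identical copies, and reads shared between copies stay open as an explanation.

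The excess on chromosome 8 was set against 3 explanations. Its number of genes cannot account for it, since the share of summits was at least 4.69 times the share of coding genes in every library. In replicates 1 to 3, it had 209, 484 and 488 summits over 1 kb from coding gene ends and 82, 94 and 233 nearer to them. The density of the former was 9.27, 18.3 and 7.03 times the median of the other autosomes. These values argue against preferred binding at its gene ends as the only source. Whether such binding adds to the excess stays open. The excess per Mb away from gene ends was 1.29, 2.58 and 2.85 times the excess per coding gene at gene ends in replicates 1 to 3. The interval of replicate 1, from resampled bins of 10 Mb, was 0.799 to 1.86. A broad regional excess of reads, such as extra DNA copies in BT549, may also explain the pattern; the density away from gene ends, at least 7.03 times the median of the other autosomes, is part of the pattern and no test of it. All 14 complete 10 Mb bins of chromosome 8 lay above the median bin elsewhere in each library, which held 1, 1 and 4 summits away from gene ends. The excess was uneven, with 3 to 46, 6 to 83 and 16 to 78 such summits per bin in replicates 1 to 3. The highest bin was the same in each library. Copy number itself was not measured here, and wide binding or open chromatin stays open.

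MHC class I genes passed with any library through replicate 3, and 3 explanations were weighed. Neighbouring genes that share 1 summit were tested by rotations of the list along the gene order, which keep neighbours together. Of the 20037 rotations, 367 gave as many genes near a replicate 3 summit (0.0183, one-sided exact share), and the highest other count was 13. The list was singled out of 15 after its values were seen, and the share is not adjusted for that, so this explanation stays open. The length of the replicate 3 list stays open: 0 MHC class I genes lay near its 1368 highest-scoring summits, but the summits at the 9 genes score 3.16 to 5.88, below the 6.56 that such a list reaches, so the count shows only that they score low. A preference for the ends of genes active in most cells also stays open. Near replicate 3 summits, 8 housekeeping families were at 1.14 times the share of all genes (Fisher's exact p = 0.0838), ZNF genes at 0.862, the other 7 families at 1.54 (exact p = 3.7e-05), and ribosomal proteins at 2.29 (exact adjusted p = 1.8e-05), against 2.60 for MHC class I; weak SOX4 binding at these genes was not tested.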
